A study of Bos taurus and Bos indicus x Bos taurus with 938 samples.

How the data were processed

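Chromatin accessibility was measured by ATAC-seq in single blastomeres of bovine preimplantation embryos made by in vitro fertilisation (IVF) or by somatic cell nuclear transfer (SCNT), in which the nucleus of a somatic cell replaces that of the oocyte. Per the labels' protocols, embryos were dissociated, each blastomere was put in its own tube with the embryo of origin recorded, and DNA was cut and tagged with Tn5 transposase in an amount set batch by batch. Per the submitters' processing notes, FastQC 0.10.1, Bowtie2 2.2.6 and bedtools were used. The genome build and the rule by which regions were chosen and called open are not given in the sources used here.

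The deposited table holds 302830 regions and 819 blastomeres, and per the file headers its regions carry only running numbers, with no coordinates and no genes. Every deposited value is 0 or 1, which was read as a closed or open call and not as a count of reads, so the depth in reads is unknown and the number of open calls per blastomere was used in its place, which ran from 519 to 129163 over the 232 embryos' blastomeres. An absent call can reflect few recovered fragments as well as closed chromatin. Coverage below means a number of open calls relative to the number expected, not read coverage. Intervals and limits from a count of 0 cover counting error only.

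Columns were tied to libraries by their numbers. The column numbers fall into 4 runs, from 1 to 259, 500 to 729, 1001 to 1212 and 1501 to 1737, whose spans of 259, 230, 212 and 237 equal the numbers of titles under the title prefixes 15243, 15244, 15286 and 15287. Each run was taken as one prefix with a constant offset of 0, 499, 1000 or 1500. This link is an inference from the numbering and is stated nowhere in the sources used here. The type of a blastomere depends only on which run it is in, while its embryo and cell number also depend on the offset. Of 938 labelled libraries, 119 have no column and were not analysed here.

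The embryo was the replicate. Groups were IVF and SCNT embryos labelled as 2-, 4- and 8-cell; embryos of other cell numbers entered no comparison. The IVF 4-cell group holds 1 blastomere whose embryo number is otherwise given to 3 blastomeres labelled 3-cell, which was taken as an embryo of its own, and 1 embryo whose number recurs under the other IVF prefix for a 6-cell embryo, which was taken as another embryo. All SCNT libraries have prefix 15243 or 15244 and all IVF libraries 15286 or 15287, and the organism label also differs between the types, so type cannot be separated from prefix or from breed. Within IVF, 64 of the 67 2-cell embryos have prefix 15286 and all 14 8-cell embryos have 15287.

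Before the data were examined, a negative binomial count test on regions and promoters, promoter shares, gene list tests and a GC correction had been planned. They were not run, since the values are binary and the regions cannot be tied to genes or positions. Regions were tested with a test chosen after the unit was known. An open call was modelled as 1 minus the exponential of minus the product of a blastomere factor and a region factor, fitted to the totals of 600 blastomeres of 192 embryos in 12 iterations. Observed and expected calls were summed per embryo over the 186 embryos with at least 1000 calls, and regions open in at least 10% of them were kept. Groups were compared by a two-sided quasi-Poisson score test whose dispersion per region and group was moderated with limma 3.58.1 in R 4.3.3. The p-value used is the larger of that p and an exact binomial p for the calls of the first group given those of both, with Benjamini-Hochberg adjustment and a threshold of 0.05.

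The exact p was added after the counts from the score test alone had been seen. That test was first run on the real data in the same step as its test on simulated data rather than after it. In simulated data without change it called 703 of 107463 regions for 8-cell against 2-cell IVF embryos of prefix 15287. It called 628 for 8-cell against 2-cell SCNT embryos of prefix 15244. Of the 9 main comparisons, it called 2 regions for SCNT against IVF 2-cell embryos and 0 in the others. With the exact p all these counts were 0. The simulation varied block coverage between embryos (SD of 0.4 in natural log) and had no loss of blocks in single blastomeres. It therefore does not give the error rate for data in which blastomeres lack blocks. Counts of the score test alone are kept as an alternative. In the simulated SCNT against IVF comparison at the 8-cell stage, which ran on 107651 regions, the final test recovered 6 of 50 regions with a 4-fold rise, 0 of 50 with a 2-fold rise, 0 of 47 with a fall to 0.5 and 1 of 41 with a fall to 0.25. In that simulation most changes of these sizes were missed.

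The order of the region numbers was examined because neighbouring regions were open in the same blastomeres. Bins of 100 regions were summed in 419 blastomeres with at least 8000 calls, and boundaries were placed where the correlation between the 10 bins on either side fell below 0.3. This left 29 blocks of 4600 to 17000 regions, a mixed segment, and 2 last blocks called P and Q here. A first scan used 0.6, which as an alternative leaves 34 blocks, and 0.3 was adopted having seen that it left 29, so that number is not independent of the choice. Relative coverage of a block is its open calls divided by those expected from the blastomere's total over the 29 blocks, over regions open in under 20% of blastomeres and in blastomeres with at least 2000 such calls. A block was called absent below 0.1; the smallest expectation was 31.2 calls. Absence was first scaled to the median block and then to the total. Unevenness is the coefficient of variation over blocks with counting error removed. All block measures were defined after the data were seen. They used 116, 59 and 88 IVF and 38, 55 and 115 SCNT blastomeres at the 2-, 4- and 8-cell stages. Blocks Q and P were related over 103 IVF and 70 SCNT embryos. The test of the difference in sister correlation between types was added late, with 10 and 51 embryos. Random pairs of the 2-cell IVF blastomeres, drawn 10000 times within prefixes, and the comparison of shifts by 1 to 3 columns in IVF 4- and 8-cell embryos were added last.

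Embryo values of 8 measures were compared in 9 comparisons by two-sided permutation tests with 100000 resamples, and the 72 p-values were adjusted together. Similarity of blastomeres of one embryo was planned before the data were examined, as the mean Jaccard index within embryos minus that between embryos of the same group and prefix after thinning to 1000 calls, with 10000 one-sided permutations. The planned number of open regions at fixed depth is void for binary values. The planned rule for named items gives 6 regions in each direction by smallest p; 2 in each direction are named, since the regions have no gene names. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used. Alternatives were other region filters, embryo depth, thinning, prefixes, scalings and block definitions.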

Results

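Open chromatin was called in single blastomeres of bovine embryos, 398 from IVF and 421 from SCNT embryos. A blastomere had a median of 8221 open regions (10770 in IVF and 6465 in SCNT), and 3.83% of all values were open calls. The design compares embryo types at the 2-, 4- and 8-cell stages and stages within a type. In cattle the main wave of embryonic genome activation falls around the 8-cell stage. The table held 67, 22 and 14 IVF embryos and 43, 25 and 21 SCNT embryos at these stages.

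SCNT blastomeres had fewer open calls than IVF blastomeres at the 2- and 8-cell stages. At the 2-cell stage the mean over embryos of the median log10 calls of their blastomeres was 3.54 ± 0.443 (SD, n = 43) in SCNT and 3.99 ± 0.327 (SD, n = 67) in IVF, a 2.86-fold difference (permutation test, adjusted p = 0.00018). At the 8-cell stage the values were 3.82 ± 0.151 (SD, n = 21) and 4.13 ± 0.274 (SD, n = 14), with an adjusted p of 0.00158, but with only embryos holding every blastomere the difference of -0.220 did not pass (unadjusted permutation p = 0.0862, n = 9 and 8). The 4-cell difference of -0.221 did not pass (adjusted p = 0.116). Every type comparison here is also one between title prefixes, so none has a within-prefix value.

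Within SCNT, log10 calls were higher at the 8-cell than at the 2-cell stage by 0.282 (adjusted p = 0.0338) and than at the 4-cell stage by 0.197 (adjusted p = 0.0381). Within prefix 15243 these differences were 0.204 (unadjusted permutation p = 0.13) and 0.179 (unadjusted permutation p = 0.0617) and did not pass. Within prefix 15244 the first was 0.501 (unadjusted permutation p = 0.00305). No IVF stage comparison passed. The change from 2 to 8 cells was not shown to differ between types (difference 0.147, permutation p = 0.278).

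**Figure D1:**
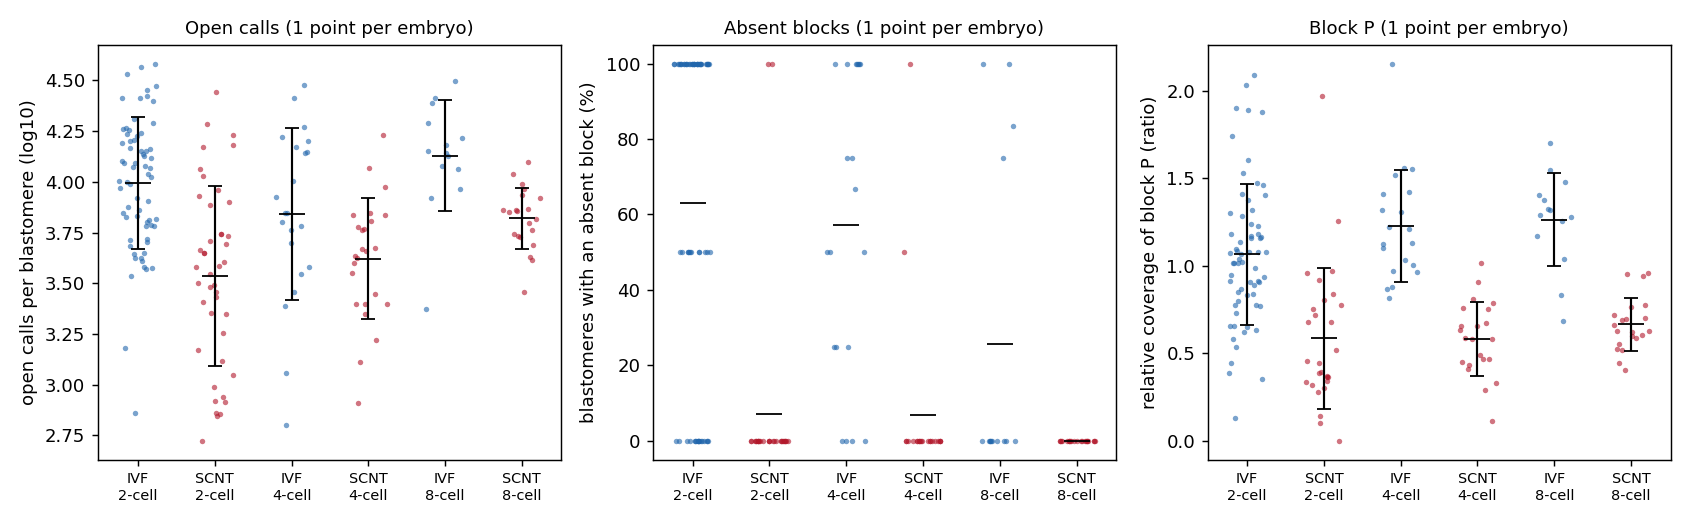
Embryo values by type and cell number, 1 point per embryo: open calls per blastomere (log10) and relative coverage of block P (ratio) with mean and SD, and percent of blastomeres with an absent block with the mean alone. All SCNT 8-cell embryos lie at 0% in the panel of absent blocks.

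Whole stretches of the region numbering had under 0.1 of their expected open calls, called absent here, in many IVF blastomeres and in few SCNT blastomeres. The numbering falls into 29 blocks within which regions were open together, with a median correlation of 0.782 inside blocks and at most 0.129 at their boundaries. At least 1 block was absent in 75 IVF 2-cell blastomeres (64.7%, exact 95% interval 55.2 to 73.3) and in 2 of 38 SCNT 2-cell blastomeres (5.26%, 0.644 to 17.8). At the 4-cell stage it was 31 of 59 (52.5%) against 5 of 55 (9.09%). At the 8-cell stage it was 22 of 88 (25%), in 4 of 14 embryos, against 0 in SCNT. That 0 allows a share of up to 2.61% (3 counts of the total), or 3.16% by the exact 95% interval. These limits and the intervals above take blastomeres as independent, although the IVF 8-cell cases were clustered in few embryos. With the 21 SCNT 8-cell embryos as replicates, a larger share is not excluded.

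Per embryo, the percent of blastomeres with an absent block was 7.14 ± 26.2 in SCNT and 63.1 ± 43.6 in IVF at the 2-cell stage (SD, n = 28 and 65, permutation test, adjusted p = 0.00018). At the 4-cell stage it was 6.82 ± 23.4 and 57.1 ± 39.7 (SD, n = 22 and 20, adjusted p = 0.00032). The 8-cell difference of -25.6 percentage points did not pass (adjusted p = 0.0672). Within IVF the difference between the 8- and 2-cell stages was -37.5 percentage points (adjusted p = 0.0277). That comparison lies mostly between title prefixes, since prefix 15287, which holds all 8-cell IVF embryos, had 3 2-cell embryos with a mean of 100%.

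Coverage over the blocks was more uneven in IVF than in SCNT 2-cell embryos, at 0.771 ± 0.258 (SD, n = 65) against 0.454 ± 0.378 (SD, n = 28, permutation test, adjusted p = 0.00018). The differences at the 4-cell stage (adjusted p = 0.0913) and the 8-cell stage (adjusted p = 0.407) did not pass. Within IVF, the 8-cell minus 2-cell difference was -0.432 (adjusted p = 0.00018) and the 4-cell minus 2-cell difference -0.194 (adjusted p = 0.0381); within prefix 15287 they were -0.403 (unadjusted permutation p = 0.07) and -0.0116 (unadjusted permutation p = 1). Within prefix 15286 the 4-cell minus 2-cell difference was -0.247 (unadjusted permutation p = 0.00185). Within SCNT, the 8-cell minus 2-cell difference was -0.209 (adjusted p = 0.0382), with -0.275 in prefix 15243 (unadjusted permutation p = 0.0206) and 0.00651 in prefix 15244 (unadjusted permutation p = 0.895).

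The blastomeres of IVF 2-cell embryos tended to mirror each other over the blocks. The correlation of log2 block coverage between sisters was -0.350 ± 0.391 (SD, 51 pairs) and negative in 38 of 51, against 0.000347 between blastomeres of different embryos (permutation p = 0.0002, the smallest they can give). In SCNT 2-cell embryos it was 0.182 ± 0.303 (SD, 10 pairs), and the difference between the types was 0.532 (permutation p = 0.00015). At the 4- and 8-cell stages the means were 0.189 and 0.321 in IVF and 0.0849 and 0.155 in SCNT. For IVF 4-cell embryos the prefixes went opposite ways, with an excess over unrelated blastomeres of 0.264 in prefix 15286 and of -0.125 in 15287. Where a block was absent from 1 IVF 2-cell sister, the median relative coverage in the other was 1.60 and 81.3% of such values lay above 1, against 0.954 and 47% on average in random pairs of the same blastomeres (permutation p = 0.0001 for each).

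**Figure D2:**
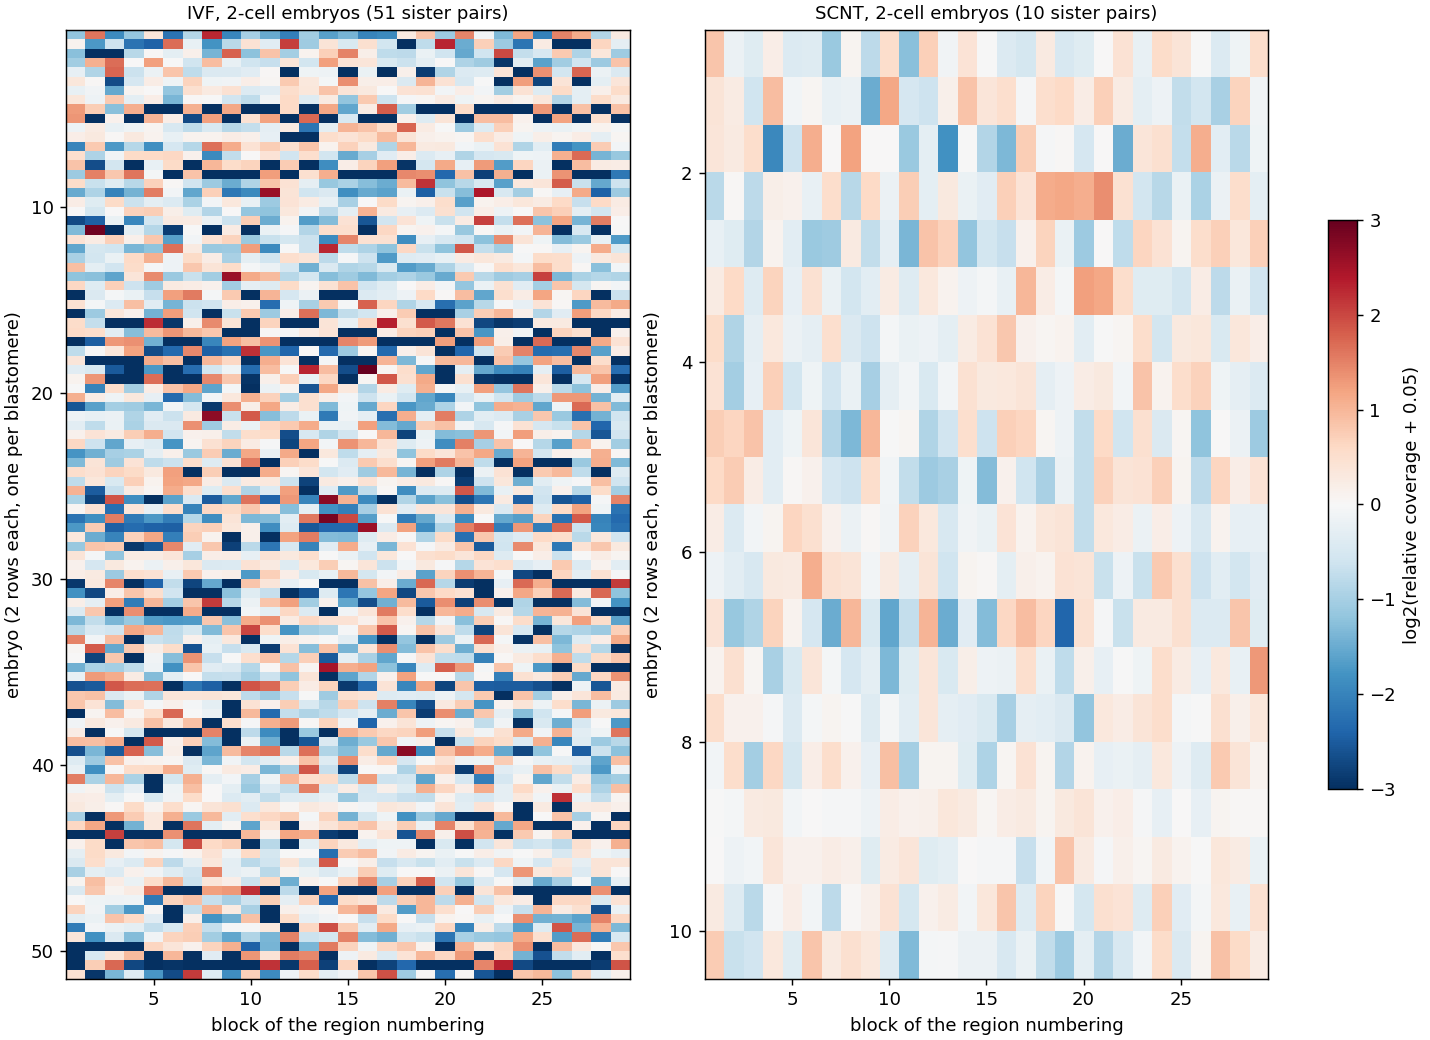
Relative coverage, as log2(relative coverage + 0.05), of the 29 blocks in the 2-cell embryos with both blastomeres, 51 IVF pairs and 10 SCNT pairs; each embryo takes 2 rows, 1 per blastomere. The dark blue cells are blocks near absence and are seen mostly in the IVF panel.

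**Figure D3:**
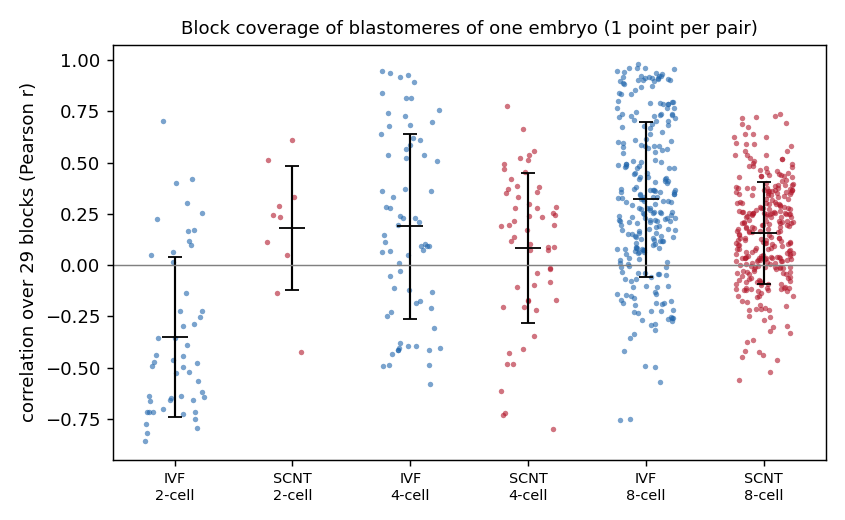
Correlation of block coverage (Pearson r over 29 blocks) between blastomeres of 1 embryo, 1 point per pair, with mean and SD by type and cell number. IVF 2-cell pairs have a mean of -0.350, and the other groups have means above 0.

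Block P, near the end of the numbering, had lower coverage in SCNT than in IVF embryos at each stage compared. Its relative coverage was 0.588 ± 0.403 against 1.07 ± 0.403 at the 2-cell stage (SD, n = 28 and 65) and 0.585 ± 0.212 against 1.23 ± 0.318 at the 4-cell stage (SD, n = 22 and 20). At the 8-cell stage it was 0.666 ± 0.153 against 1.27 ± 0.268 (SD, n = 21 and 14). Each difference had an adjusted p of 0.00018 by permutation. Block Q was higher in SCNT at the 2-cell stage (1.42 against 0.811, adjusted p = 0.00234) and the 8-cell stage (1.38 against 0.813, adjusted p = 0.00018), and did not pass at the 4-cell stage (1.36 against 0.913, adjusted p = 0.0501). Over its singly tested regions with calls in both types, the median log2 ratio was -0.26, -0.39 and -0.27 at 2, 4 and 8 cells. Regions with calls in 1 type only have no finite ratio and are left out of these medians. No comparison passed for the percent of calls in the mixed segment or in commonly open regions.

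Among 91058 regions tested singly without thinning, the 8-cell stage had the most that differed between types. There 1348 regions were open more often in SCNT and 1314 less often (limma-moderated score test with exact bound, adjusted p under 0.05). Region V278108 of the mixed segment had 64 calls in SCNT and 5 in IVF, a log2 ratio of observed over expected calls of 4.09 ± 0.69 (SE, adjusted p = 3.76e-11). Region V107404 of block 11 had a log2 ratio of 2.35 ± 0.34 (SE, adjusted p = 4.6e-10). Among regions less often open, V100164 of block 10 had 3 and 56 calls, at -3.80 ± 0.87 (SE, adjusted p = 1.13e-05). V294537 of the mixed segment had 9 and 67, at -2.50 ± 0.52 (SE, adjusted p = 4.47e-05). In block P 8 regions were higher and 86 lower, and in block Q 24 were higher and 8 lower. The balance of directions rests on the scaling, since 75.4% of called regions were higher with depth taken from commonly open regions against 50.6%. With embryos thinned to equal totals no region passed at 8 cells, 0 at 4 cells and 1 at 2 cells, with 3.99%, 2.82% and 2.46% at an unadjusted p under 0.05.

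At the 2-cell stage 39 regions were higher in SCNT and 1 lower. At the 4-cell stage 8 were higher and 0 lower, with 3742 (4.11%) at an unadjusted p under 0.05. The 4-cell counts were 54 and 12 with a filter at 25% of embryos, and 69 and 0 with depth from commonly open regions. Of the 39 2-cell regions, 27 were also higher at the 8-cell stage, where independent lists would share 0.577, and 0 went the opposite way. Of the 8 4-cell regions, 4 were also higher at 2 cells and 7 at 8 cells, where independent lists would share 0.00343 and 0.118. Those comparisons share no embryos, but the values for independent lists take every tested region as equally likely to be called. The calls were not spread evenly. Of the 39 2-cell regions, 14 lay in block Q, 12 in the mixed segment, 12 in the 29 blocks and 1 in block P. That is 6.25% of the tested regions of block Q and 0.0151% of those of the 29 blocks. The overlaps were not counted by part, so how far they rest on block Q is not known. Across 12705 regions the log2 ratios of the 2- and 8-cell stages had a Pearson's r of 0.114 and a Spearman's rho of 0.0955, against 0.549 and 0.524 for 2 and 4 cells and 0.334 and 0.312 for 4 and 8 cells over other region sets; regions are not independent replicates. Without blastomeres that lacked a block no region passed at 2 or 4 cells, with 2.9% and 4.35% at an unadjusted p under 0.05, while 2567 passed at 8 cells.

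Within IVF, 7139 regions were higher and 3050 lower at the 8-cell than at the 2-cell stage (same test), so that 70.1% were higher. The direction varied with how often a region was open. Among regions with a call in 10 to 25% of embryos 4756 were higher and 2336 lower, and at 25 to 50% 2313 and 410. At 50 to 75% 70 were higher and 289 lower, and at 75% and over 0 and 15. With depth taken from commonly open regions 21.8% were higher, which turns the direction. The median log2 ratio over tested regions with calls at both stages moved from -0.17 to -0.67. Without blastomeres found to lack a block 297 regions passed, and 12.8% of them were higher. Within prefix 15287, with 3 2-cell embryos, 0 passed and 1.78% of regions had an unadjusted p under 0.05. Between the 4- and 2-cell stages 10 regions were higher and 0 lower, with 5170 (5.68%) at an unadjusted p under 0.05. Between the 8- and 4-cell stages 0 passed, with 8025 (8.81%) at an unadjusted p under 0.05.

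Within SCNT 0 regions passed in each stage comparison by the limma-moderated test, and the score test alone also gave 0. An unadjusted p under 0.05 was found for 2426 regions (2.66%) for 8 against 2 cells. It was found for 1.24% of regions for 4 against 2 and for 1904 (2.09%) for 8 against 4. A lesser change in SCNT than in IVF is not shown by these counts. The direct test of the difference in change called 0 of 12705 regions, with 2048 at an unadjusted p under 0.05. That share is above 0.05, so a difference in change is not excluded. The direct test had no exact bound. It covered only regions with at least 5 calls in each of the 2- and 8-cell groups of both types, so regions nearly closed in a group were not tested.

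Blastomeres of 1 embryo shared more open regions than blastomeres of different embryos at the 4- and 8-cell stages. At 1000 calls each, the Jaccard index within embryos exceeded that between embryos by 0.00458 in IVF 8-cell, 0.00229 in SCNT 8-cell and 0.00322 in SCNT 4-cell embryos (permutation p = 0.0001, the smallest they can give, adjusted p = 0.0002 over 6 groups). In IVF 4-cell embryos the excess was 0.00229 (adjusted p = 0.011). In 2-cell embryos it did not pass, at 0.000628 in IVF (adjusted p = 0.0948) and -0.000478 in SCNT (adjusted p = 0.73). At 5000 calls the SCNT 4-cell excess of 0.00324 did not pass (permutation p = 0.062), and the IVF 2-cell value turned to -0.00442 (permutation p = 1 for an excess). The highest Jaccard index of any pair of libraries was 0.390, between libraries with 4145 and 3841 calls. They were assigned to different SCNT 8-cell embryos whose titles follow each other. At 5000 calls the SCNT 8-cell means were 0.0519 within and 0.0433 between embryos. Whether the libraries of that pair are independent was not tested.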

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

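Most tests in this part were chosen after the results were seen; only the overall comparison with column numbers shifted by 1 to 3 and the relation of block Q to block P were fixed before their results, and the separate readings of odd shifts and of shifts by 2 were not.

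Among embryos outside the compared stages, 30 of 70 IVF blastomeres (42.9%) lacked a block, in 9 of 18 embryos, and 0 SCNT blastomeres did, in 20 embryos (Fisher's exact test over embryos, p = 0.000298), a signal in embryos that no comparison uses. In the IVF 6-cell group 1 embryo stood far from the other 5, with 8.8 absent blocks per blastomere where the next had 1, and an unevenness of 1.37 where the next had 0.439. In the SCNT 6-cell group 1 embryo had the lowest coverage of block Q, 1.255 against 1.38 for the next of 5. Of 28 groups tested for such an embryo 3 had one, 2 of them the same IVF 6-cell group under related measures, and chance gives about 1 in 20. The correlation between 2-cell sisters differed between the types by 0.532.

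The excess of absent blocks in IVF blastomeres was weighed first. Among blastomeres with at least 2000 block calls, depth is argued against by a 2-cell difference of -58.2 percentage points after thinning to 2000. Those blastomeres came from 28 of 43 SCNT and 65 of 67 IVF 2-cell embryos, and an effect of that selection was not tested. Loss of DNA tube by tube as the only cause is argued against in 2-cell IVF embryos by their sisters, 49 of 51 pairs being of prefix 15286. Sisters differed from unrelated blastomeres by -0.351, where such loss alone gives 0. Such loss beside another cause is not excluded, and loss at 4 and 8 cells was not weighed. Where only some blastomeres of an IVF embryo lacked a block, 59.4% of the others' values lay above 1 at 4 cells and 55% at 8 cells. In prefix 15286 odd shifts of the column numbers are argued against by 2-cell embryos, at no more than 0.0092 in size. In 15287 they stay open, since 4- and 8-cell embryos lay -0.445 standard errors from an odd shift. They stay open in SCNT too, where 4-cell embryos of 15243 gave 0.119 at an odd shift and 0.0785 at the assumed link. The other SCNT groups were higher at the assumed link than at any odd shift. The values were 0.147 against at most 0.0622 in 2-cell and 0.1335 against at most 0.1287 in 8-cell embryos of 15243. In 8-cell embryos of 15244 they were 0.116 against at most 0.111. At shifts by 2 the SCNT 2-cell embryos of 15243 gave 0.174 and 0.190, above their 0.147 at the assumed link. The other SCNT groups gave less at shifts by 2 than at the assumed link. The most similar pair of libraries (Jaccard index 0.390) was assigned to different 8-cell embryos of 15243 whose titles follow each other. Whether wrong numbering accounts for that pair was not tested. IVF 4-cell embryos of 15287 gave -0.0997 and 0.00928 at shifts by 2 and -0.125 at the assumed link. In prefix 15286 a shift by 2 gave 0.340 against 0.352 at the assumed link, a gap under the standard error of 0.0547, because such shifts keep most 2-cell sisters paired; IVF 4- and 8-cell embryos exceeded their values at shifts of 2 by only 0.742 to 1.44 standard errors, so these shifts cannot be told apart although the bound fixed beforehand was met. The 0 title prefixes with both types leave title prefix and type impossible to separate, and unequal sharing of chromosomes between sisters stays open too: the other sister lay above 1 in 81.6% of 38 embryos against 55.1% on average in random pairs (permutation p = 0.0001), but this restates the negative correlation of the same pairs.

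The lower coverage of block P in SCNT was weighed next. Among blastomeres with at least 2000 block calls, depth is argued against by a thinned 8-cell difference of -0.628. A difference in sex between the embryo sets may lower a block on a sex chromosome. Within a type that holds both sexes, the 24 block Q regions that were higher in SCNT 8-cell embryos would then be rarer where P is high. Whether either type holds both sexes is not known here, so the correlations within a type cannot decide. Among IVF embryos outside the 8-cell group, of which all but a 2-cell embryo (12 calls, P at 0.388) and a 13-cell embryo (21 calls, P at 1.06) had at most 5 such calls, Spearman's rho was -0.150 (permutation p = 0.13) and Pearson's r -0.206 (permutation p = 0.05), or -0.149 and -0.210 without the 2 embryos farthest from the median of P, while among 70 SCNT embryos rho was -0.296 (permutation p = 0.014) and r -0.192 (permutation p = 0.11), or -0.318 for both without the 2 farthest, so sex stays open. With 0 title prefixes holding both types, title prefix stays open too.

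The excess of regions that were higher over lower in 8-cell than in 2-cell IVF embryos was weighed last. It depends on the scaling, since 21.8% of called regions were higher with depth from common regions. Title prefix cannot be told apart from stage, since 0 regions passed within prefix 15287, where only 3 2-cell embryos remain. No biological explanation was tested.

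Chance division of the embryos was tested with 100 splits per comparison, the real one included. For SCNT against IVF it is argued against at 2 cells (1 split as large, real 40, highest other 0). The same holds at 8 cells (1 split as large, real 2662, highest other 261). At 4 cells it is not excluded, since another split gave 14 regions against the real 8 (2 splits as large, the real one included). In IVF it is argued against for 8 against 2 cells (1 split as large, real 10189, highest other 1.48% of it) and for 4 against 2 cells (1 split as large, real 10, highest other 0). For the 4 comparisons with 0 regions the splits decide nothing, since all 100 must give as many; the highest other was 0 for 8 against 4 cells in IVF, and in SCNT 2, 0 and 1 for 8 against 2, 4 against 2 and 8 against 4 cells. Splits mix title prefixes, so they do not bear on them.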

How the results depend on the processing

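Alternatives that change the score test, the block definitions, the blastomeres kept or the scaling were chosen after seeing the data; filters, embryo depth, thinning and prefixes were planned. Embryo measures are judged here at an unadjusted p of 0.05. The cause of each change was not tested, and where fewer embryos or calls are stated they describe the alternative only. Counts of regions are given in the order SCNT against IVF at 2, 4 and 8 cells, then IVF 8 against 2 and 4 against 2 cells, whose main counts were 40, 8, 2662, 10189 and 10. The score test alone, which was run first, gave 486, about 1.1e+02, 3589, 15531 and 324. A filter at 25% of embryos gave 14, 66, 1273, 3940 and 11, and at least 10 calls in all gave 29, 4, 1318, 10828 and 1. Embryos with at least 10000 calls gave 14, 3, 2273, 10522 and 10. Thinning embryos to 10463 calls left 13953 regions and gave 1, 0, 0, 4 and 0, so that at most 4 regions passed at that shallow depth. Without blastomeres that lack a block the counts were 0, 0, 2567, 297 and 0, from fewer embryos and 57103 regions. Depth from common regions gave 43, 69, 2161, 14944 and 1, and depth within each part of the numbering 25, 33, 2009, 8797 and 6. For IVF 8 against 2 cells prefix 15287 alone and prefix as a stratum gave 0; for 4 against 2 cells prefix 15286 gave 1, 15287 gave 0 and the stratum 1. For SCNT 8 against 2 cells prefix 15244 alone gave 1.

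For log10 calls, only embryos with every blastomere gave -0.179 and -0.220 for SCNT against IVF at 4 and 8 cells, 0.201 for IVF 8 against 4 and 0.159 for SCNT 8 against 4, none past the threshold; so did single prefixes, at 0.309 for IVF 8 against 4, 0.204 for SCNT 8 against 2 (but 0.501 and past it in prefix 15244) and 0.179 for SCNT 8 against 4. The share of blastomeres with an absent block in IVF 8 against 4 cells lost its call within prefix 15287 (-9.41), with absence below 0.05 (-17.9) and with all regions (-24.8), while SCNT 8 against 2 cells passed with absence below 0.2 (-21.4). The SCNT against IVF differences in that share (6 alternatives per stage) and in block P (3 per stage) kept their direction and side of the threshold, at -41.0 to -65.9 and -0.498 to -0.511 at 2 cells; the number of absent blocks per blastomere at 4 cells did not pass in 3 of its alternatives. Unevenness in SCNT 8 against 2 cells reversed within prefix 15244 (0.00651) and was -0.275 within the larger prefix 15243. Sister similarity in SCNT 4-cell embryos was 0.00324 at 5000 calls and no longer passed, and in IVF 2-cell embryos it turned to -0.00442. No planned promoter, gene list, promoter share, GC, size factor or open-region alternative was run, since values are binary and regions have no position; library size is the main scaling. No paired analysis was possible because the groups share no replicate numbers.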

Other observations

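The test in this part was chosen after the block sizes had been seen. The 29 blocks may be the 29 bovine autosomes listed in text order (1, 10 to 19, 2, 20 to 29, 3 to 9). Regions per block correlated with genes per autosome of the ARS-UCD2.0 gene table in that order with Spearman's rho of 0.666 (permutation p = 0.0004, one-sided), against -0.13 in numerical order (p = 0.75). The number of blocks was fixed with a threshold that was seen to give 29, and no region has a coordinate, so the identity of blocks, P and Q included, stays a hypothesis.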
